A study of Homo sapiens with 8 samples.

How the data were processed

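RNA sequencing libraries of H295R cells, an established human adrenocortical carcinoma line that makes steroid hormones, were compared between control clones and clones in which FSCN1 had been knocked out. FSCN1 encodes fascin, a protein that bundles actin filaments. The labels give 2 clones per genotype and 2 biological replicates per clone, called cultures here, for 8 libraries in all. Replicates 1 and 2 of a genotype are the cultures of its clone 1, and replicates 3 and 4 those of its clone 2. Total RNA was extracted with Trizol and made into stranded libraries after removal of ribosomal RNA, per the labels' protocols. How the gene was disrupted is not given in the sources used here.

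The authors deposited a table of 28278 gene symbols by 8 libraries. Its values are a signal that is never negative: read counts per gene divided by a size factor per library, which the authors made with DESeq2, per the labels. Per the submitters' processing notes, the tools used were FastQC, Trimmomatic, STAR, featureCounts and DESeq2, with the human genome build hg38; their versions, the annotation and the strand setting of the counting are not given in the sources used here. Because the strand setting is not stated, overlapping and antisense genes may share reads, and paralogs may too. All 8 columns were matched to samples by their names.

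The deposited values were whole multiples of a step in each library, so that whole reads could be recovered: 100.0% of the values came out whole within a tolerance of 0.01. The recovered totals were 26477383 to 31729472 reads per library. These totals count reads assigned to genes only. No gene of the mitochondrially encoded list was in the table, so this list was not analysed here.

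The comparison of genotypes was fitted with limma 3.58.1 in R 4.3.3 on log2 of the normalised count plus 1, with a variance prior that follows the mean. A fold change on this scale understates the change of genes with few reads. The 15321 genes with a mean normalised count of at least 10 over the 8 libraries were tested. Clone entered as a random block, since libraries of the same clone are not independent samples of a genotype; the fitted correlation within clones was 0.412. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts of single clones came from a limma fit with 4 clone terms, whose p-values measure the spread between cultures of a clone and not the spread between clones. The tests were two-sided.

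The designs, the alternatives, the rule for named genes and 30 gene lists holding 1011 genes were fixed before the data were examined; 29 lists had tested members. Lists were tested with limma's cameraPR at a preset correlation of 0.01 between genes, adjusted over the lists. The same lists were tested with camera at an estimated correlation and with fry. Between genotypes, camera had no clone block and treated the 8 libraries as independent, while fry kept the block. The camera check thus differs from cameraPR in more than the correlation. The rule for named genes took FSCN1, up to 12 genes per direction among genotype calls with a mean of at least 50, up to 4 members of each list with the smallest p, and the 5 largest differences per direction between clones of a genotype, of which 1 is not reported. The genotype part of this rule named 0 genes, because the test called none. A further rule was therefore chosen after the values were seen: up to 12 genes per direction that were called the same way in both KO clones, had a mean of at least 50 and had every KO library beyond every control library, ranked by log2 fold change. In both rules, symbols in the style of noncoding RNAs, or ending in P with or without digits as those of pseudogenes do, were not named. This left out 2 genes that are not pseudogenes, PALM2AKAP2 and NLRP1, which are given beside the others. The count of genes separating both KO clones from both control clones, in which all 4 contrasts of a KO clone with a control clone pass in the same direction, was also chosen after the values were seen. Members of lists given beyond the first 4 were likewise chosen after their values were seen.

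Alternatives were other pseudocounts, filters and scalings, a prior without a trend, fits without the clone block or on clone means, a fit with the culture number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library or clone. Where this left a clone with 1 library, that library was assumed to vary like those of the other clones. Where a clone was left out, its genotype kept 1 clone, so genotype and clone could not be told apart there. edgeR and DESeq2 treated the 8 libraries of the genotype comparison as independent. Results that share control libraries were set beside 50 simulations in which clones differ by chance alone. Gene positions came from an annotation of assembly GRCh38.p14 for 98.5% of the tested genes, and GC content from GENCODE transcripts for 94.2%.

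The fits were tested on simulated reads with known changes. Clone differences were drawn at random, with a variance of 0.412 times that of each gene in the genotype fit. Reads within a clone varied by the dispersions that edgeR estimated, so their correlation within clones was not fixed at 0.412. With these clone differences and 200 genes changed, the genotype fit recovered 76.3% of 2-fold and 96.2% of 4-fold changes. It made 41.8 false calls per run over 15200 genes. With 20 changed genes it recovered 62% of the 2-fold changes, and 82 of its 157 calls over 5 runs were false. In a simulated set with clone differences, DESeq2 made 275 false calls over 15215 genes, and in a set without them it made 24 over 15226 genes. The corresponding false calls of edgeR were 139 and 14. The contrast of KO clone 1 with controls recovered 82.6% of 2-fold changes, with 12.4 false calls per run over 15234 genes, when clones did not differ otherwise. With clone differences drawn as above it made 813.4 false calls per run over 15200 genes. Calls of a single KO clone therefore include differences between clones whatever their genotype. Log2 values simulated with the same clone term gave 285.44 calls between KO clones and 292.4 between control clones on average. The libraries gave 1601 and 1258, so the simulated rates may not carry over to them.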

Results

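Messenger RNA levels were measured in 4 control and 4 FSCN1 knockout (KO) libraries of H295R cells, with 2 cultures of each of 2 clones per genotype. The libraries held 26477383 to 31729472 recovered reads and 18989 to 19513 genes above 0. The 10 most abundant genes took 12.96% to 20.18% of the counts, the largest share being in culture 1 of KO clone 2. RN7SL1 or RN7SK, both small structural RNAs, was the most abundant gene of every library. Cultures of a clone differed by more than sampling noise, with a chi-square per gene of 11.26 to 34.37, so no library was a copy of another. The design asks what loss of fascin changes in these cells and whether clones of the same genotype share the change.

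FSCN1 lies on the plus strand of chromosome 7 at 5592823 to 5606655 (GRCh38, GENCODE release 29, ENSG00000075618.17), and the counts cover the whole gene, not a part of it. Its normalised read count was 7244 ± 552 (SD, n = 4 libraries) in controls and 2800 ± 1008 (SD, n = 4) in KO libraries, or 38.65% of the control level. The control libraries held 6526, 7602, 7745 and 7102. The libraries of KO clone 1 held 3381 and 3876, or 50.08% of the control mean, and those of KO clone 2 held 1670 and 2274, or 27.22%. Every KO library was below every control library (exact two-sided permutation p = 0.0286, the smallest the 70 splits allow). The 4 clones alone cannot give an exact p below 0.333. The log2 fold change was -1.44 (SE 0.23) with clone as a block, with a limma adjusted p of 0.146 over all genes. FSCN1 ranked 3 by p. DESeq2 on recovered reads gave -1.37 with an adjusted p of 5.02e-07. Without KO replicate 3, culture 1 of KO clone 2, limma gave -1.28 with an adjusted p of 0.0223. FSCN1 was lower in KO clone 2 than in KO clone 1 by a further log2 of -0.89 (SE 0.14, limma adjusted p = 0.000715).

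**Figure D1:**
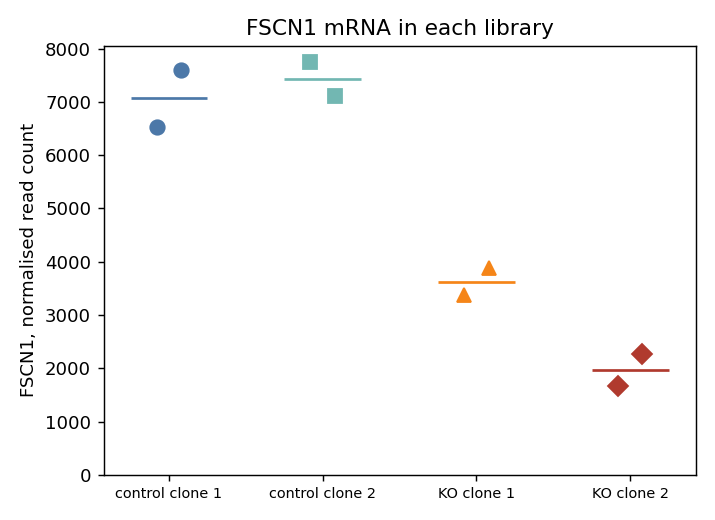
FSCN1 normalised read count (vertical axis, starting at 0) in each of the 8 libraries, by clone; each point is a culture and each line the mean of a clone. Clone means were 7064 and 7424 in controls, 3628 in KO clone 1 and 1972 in KO clone 2.

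Libraries grouped by clone more than by genotype. The first principal component of the tested genes held 38.4% of the variance and set control clone 1 apart, at -45.95 and -39.32, from the other 6 libraries, which lay between 0.43 and 40.56. The second held 24.5% and set KO clone 2 (30.33 and 18.11) against KO clone 1 (-28.19 and -33.42). Control clone 2 lay between the KO clones on this axis, at -13.79 and 0.28.

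**Figure D2:**
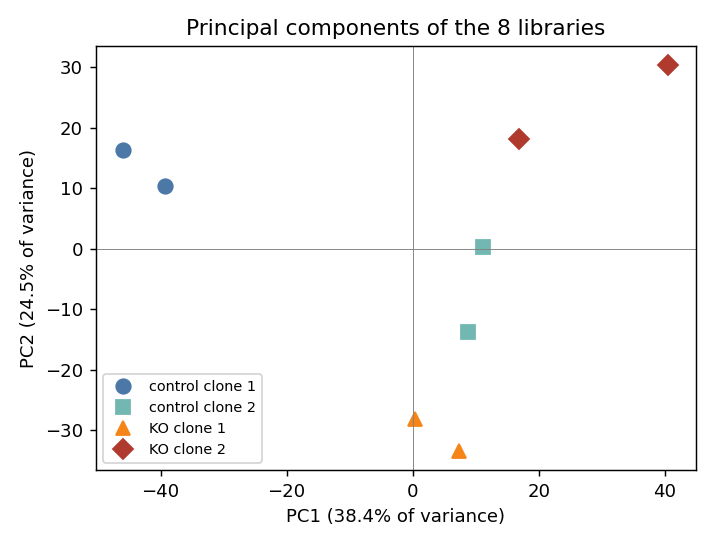
First and second principal components of the 8 libraries, in percent of variance on each axis; points are cultures, and shapes and colours are clones. Control clone 1 stands apart on the first axis at -45.95 and -39.32, and the KO clones lie at opposite ends of the second.

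Between genotypes, no gene passed the test. The genes nearest to it were ADAMTS18, a secreted metalloproteinase (log2 -2.42, SE 0.36), FREM2, a basement membrane protein (-1.34, SE 0.19), and FSCN1; the smallest limma adjusted p was 0.104. limma with clone as a block called 0 of 15321 genes, with 911 at an unadjusted p under 0.05, and 0 genes at least 2-fold. edgeR called 2 genes, ADAMTS18 and FREM2, both lower in KO. DESeq2 called 126 genes, 80 higher and 46 lower in KO, of which 43 changed at least 2-fold; its adjusted p was not computed for 2 genes. Of the 126, 85 were called in the same direction in both KO clones and 113 had no overlap of KO and control libraries. Both counts follow in part from picking the 126 on the same libraries. Of all tested genes, 7.11% had no overlap, and 150 were called higher and 94 lower in both KO clones. Without control clone 2, limma called 312 genes, without KO clone 2 it called 15, and without KO replicate 3 it called 6. In the fits without a clone, 1 genotype kept 1 clone, so genotype and clone cannot be told apart.

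Genes that separated each KO clone from each control clone numbered 7. SCIN, an actin-severing protein of the gelsolin family (log2 1.59, SE 0.29), and PALM2AKAP2, an anchor of protein kinase A (1.39), were higher in KO. ADAMTS18, FSCN1, FREM2, the acute-phase protein gene ORM1 (-0.93) and the transporter SLCO5A1 (-0.82) were lower. Other pairings of the 4 clones gave larger counts: 27 genes separated control clone 1 and KO clone 1 from the other clones, and 72 separated control clone 1 and KO clone 2 from the others. These counts also moved with single libraries. Without control replicates 1 to 4 the 27 became 11, 6, 11 and 4, and without KO replicates 1 to 4 it became 4, 1, 66 and 112, which equals the real count without control replicate 2 or 4 or KO replicate 2. The 72 became 41, 49, 21 and 72, and 31, 27, 86 and 123, above the real count each time. The count fell to 1 without KO replicate 2, to 2 without KO replicate 1 and to 4 without control replicate 3 or 4, and it rose to 36 and 40 without KO replicates 3 and 4. Simulated log2 values of clones that differ by chance gave 3.78 such genes on average and 8 at most. Simulated reads of clones that differ by chance, with 200 genes changed, gave 20.8 unchanged genes per run that separated, so that 7 is not above what chance can give.

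Among the genes called in the same direction in both KO clones, no shared function was tested. FN1, which encodes fibronectin, averaged 217.1 and 249.5 normalised counts in the control clones against 387.1 and 677.1 in KO clones 1 and 2. CD44, a hyaluronan receptor, averaged 27.97 and 58.43 against 101.5 and 97.82. FOS, part of the AP-1 transcription factor, averaged 18.77 and 35.01 against 55.41 and 136.5. The other genes of this set that were higher were SCIN, TSPAN18, ATCAY, NPR3, PROK1, DACH2, ANO4, FAM83G and NSUN5, with log2 fold changes between genotypes of 1.11 to 1.59. PALM2AKAP2 (1.39) met the same criteria in all but its symbol. Among the lower genes, PAK3, a p21-activated kinase, averaged 141.9 and 51.73 in control clones against 24.11 and 13.52. PKIA, an inhibitor of protein kinase A, averaged 1370 and 415.1 against 329.5 and 303.3, and the protocadherin PCDH17 averaged 108.9 and 115.7 against 37.3 and 52.82. CCSER1, HCRTR2, RIMS4, TCIM, CTNNA3 and LPAR4 were also lower, by log2 -1.03 to -1.54. These genes were selected on the values given. The control clones differed from each other for some of them, such as PKIA, SCIN and NSUN5.

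**Figure D3:**
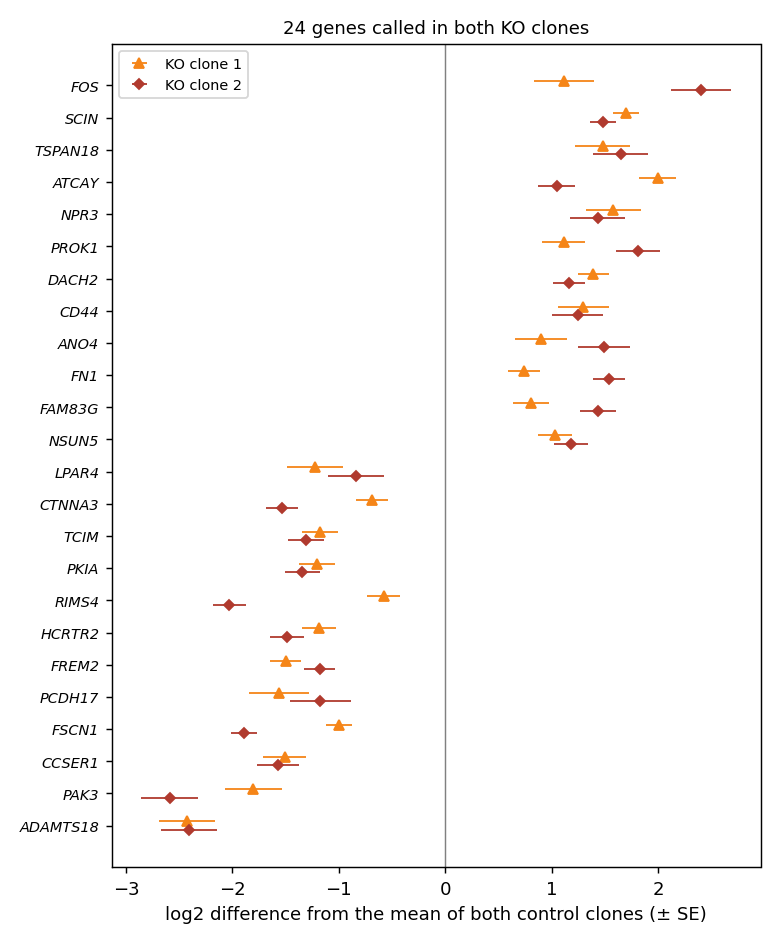
Log2 difference of KO clone 1 (triangles) and KO clone 2 (diamonds) from the mean of both control clones for 24 genes called in both, with bars of ± SE from the limma fit. ADAMTS18 is lowest, at -2.42 and -2.41, and FOS reaches 1.12 and 2.40.

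Targets of the transcription factor SRF and its actin-regulated cofactors (MRTF) were higher in KO as a group. Of 22 measured genes, 18 had a positive log2 fold change, with a median of 0.41 (limma cameraPR adjusted p = 2.78e-08; adjusted p = 0.088 with an estimated correlation; fry adjusted p = 0.0237). Among them were FOS (log2 1.76, SE 0.46), EGR1 (1.48, SE 0.45), ZYX, which encodes the focal adhesion protein zyxin (0.52, SE 0.16), and TAGLN2, an actin-binding transgelin (0.53, SE 0.18). None of the 22 was called over all genes, and 3 (FOS, EGR1 and ZYX) were called adjusted over the list alone. The list was higher in KO clone 1 (median 0.32, adjusted p = 0.00018) and KO clone 2 (0.53, adjusted p = 5.05e-09), but neither call held with an estimated correlation (adjusted p = 0.571 and 0.38). In each of the 4 pairs of a KO clone with a control clone the median was above 0, at 0.24 to 0.44. The 2 control clones gave adjusted p = 0.676.

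**Figure D4:**
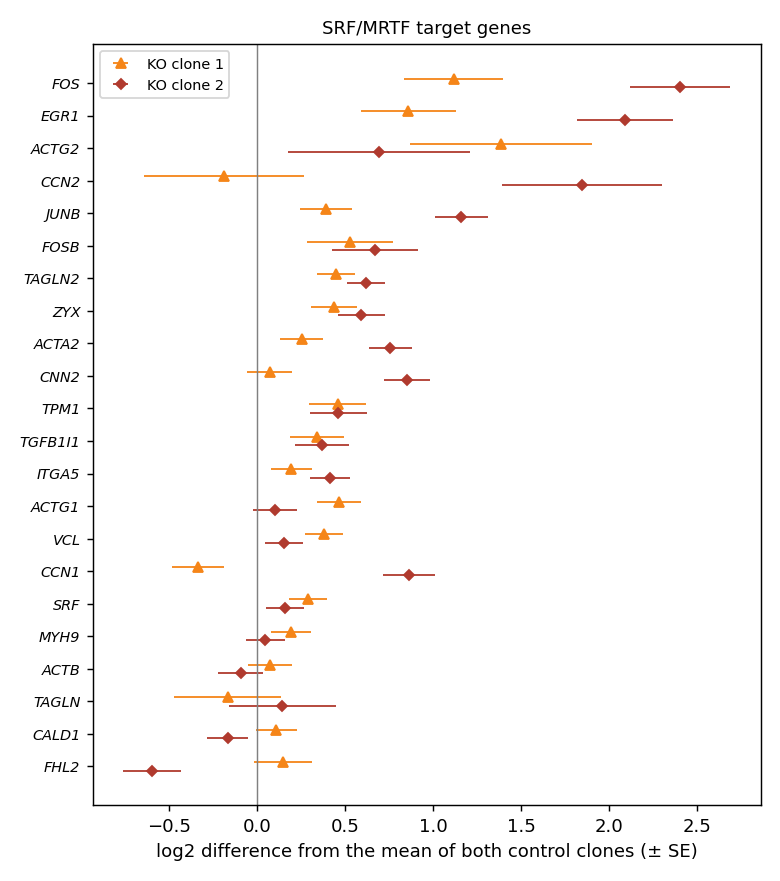
Log2 difference of KO clone 1 (triangles) and KO clone 2 (diamonds) from the mean of both control clones for the 22 measured SRF/MRTF targets, with bars of ± SE from the limma fit. FOS and EGR1 lie highest, while CCN1 was at -0.33 in KO clone 1 and 0.86 in KO clone 2.

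Fibrillar collagen and matrix genes were also higher as a group: 29 of 38 had a positive log2 fold change, with a median of 0.30 (cameraPR adjusted p = 7.66e-05; adjusted p = 0.088 with an estimated correlation; fry adjusted p = 0.134). FN1 (log2 1.14, SE 0.24) was called adjusted over the list alone, and none was called over all genes. LOXL2, a lysyl oxidase (0.99, SE 0.31), COL5A1 (0.66, SE 0.22) and LAMA5 (0.66, SE 0.25) had the next smallest p. Medians were 0.24 in KO clone 1 and 0.25 in KO clone 2, and 0.23 to 0.28 in the 4 clone pairs. Beside this list, 6 fibroblast markers had a median of 0.46 (cameraPR adjusted p = 0.0349, camera adjusted p = 0.468 with an estimated correlation, fry adjusted p = 0.00523). FBLN1, COL1A1 and COL3A1 are on both lists. The fibroblast call held in 16 of 26 alternatives. It was lost on clone means and without the clone block, among others. It ended without control clone 2 (adjusted p = 0.294), KO clone 1 (adjusted p = 0.148), control replicate 3 (adjusted p = 0.0587) or KO replicate 1 (adjusted p = 0.0758). COL3A1 averaged 1093 and 427.4 in control clones, 559.5 in KO clone 1 and 3971 in KO clone 2. Endothelial (adjusted p = 0.354) and leukocyte markers (adjusted p = 0.635) did not pass.

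The other 6 lists past the preset-correlation test shifted less, and each lost its call with an estimated correlation. Replication-dependent histone genes were lower, 11 of 51 being positive (median -0.13, adjusted p = 0.000569; adjusted p = 0.564 with an estimated correlation). Cell cycle genes were lower, 13 of 50 being positive (median -0.10, adjusted p = 0.026; 0.564 is the adjusted p with an estimated correlation). Wnt/beta-catenin targets were higher, with CD44 and ISM1 among them (median 0.11, adjusted p = 0.0339; adjusted p = 0.564 with an estimated correlation). Axon guidance genes were higher, with SLIT3 at 0.82, SE 0.21 (median 0.17, adjusted p = 0.0476; adjusted p = 0.564 with an estimated correlation). Cholesterol biosynthesis genes were lower (median -0.25, adjusted p = 0.0434; adjusted p = 0.712 with an estimated correlation), though ABCA1, which exports cholesterol, was at 0.98, SE 0.24. Unfolded protein and integrated stress response genes were lower, with PSAT1 at -0.70, SE 0.31 (median -0.15, adjusted p = 0.0401; adjusted p = 0.712 with an estimated correlation). Without control clone 1 the Wnt/beta-catenin and cell cycle medians were -0.018 and -0.006 (adjusted p = 0.971 and 0.966), and against control clone 2 alone the Wnt/beta-catenin median was -0.058 in KO clone 1 and 0.005 in KO clone 2. Without KO clone 2 the cholesterol median was 0.02, and without KO clone 1 the axon guidance and stress response medians were -0.12 and 0.03. With a trend on GC content removed from each library, the axon guidance median was 0.04 (adjusted p = 0.478) and the Wnt/beta-catenin call ended (0.11, adjusted p = 0.0552). Leaving out single libraries ended calls of all 6 lists. The histone call ended without KO replicate 1 (adjusted p = 0.153), and also without control clone 2 (adjusted p = 0.365) and without KO clone 1 (adjusted p = 0.204). Calls also ended without KO clone 2 for cell cycle (adjusted p = 0.441), without KO clone 1 or 2 for Wnt/beta-catenin targets (adjusted p = 0.0654 and 0.275), without control clone 1 for cholesterol (adjusted p = 0.971), and without control clone 2 for axon guidance and stress response (adjusted p = 0.232 and 0.281). The cell cycle and Wnt/beta-catenin calls ended without control replicate 1 (adjusted p = 0.0761 and 0.103) and without KO replicate 3 (adjusted p = 0.0857 and 0.108). The cholesterol call ended without control replicate 1, 2 or 3 or KO replicate 1 or 3 (adjusted p = 0.0537 to 0.987), and the stress response call without control replicate 3 or KO replicate 1, 2 or 4 (adjusted p = 0.101 to 0.524). The axon guidance call ended without control replicate 1, 3 or 4 or KO replicate 1, 2 or 4 (adjusted p = 0.053 to 0.168).

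Actin-bundling genes other than FSCN1 did not shift as a group. With FSCN1 the list of 25 had a median of 0.06, a mean of -0.07 and a downward test (limma cameraPR adjusted p = 0.496). Without it the median of 24 genes was 0.07 (limma cameraPR adjusted p = 0.911). MARCKS, which crosslinks actin, was at -0.80, SE 0.18, called adjusted over the list alone and not over all genes. Steroidogenic genes, which set the hormone output of these cells, had a median of -0.07, a mean of 0.09 and a downward test (adjusted p = 0.722). The members with the smallest p were CYP11B2, HSD3B1, CYP19A1 and HSD17B12. With a GC trend removed they were at log2 1.24, 1.54, -0.64 and -0.19 between genotypes. Without its removal, CYP11B2, HSD3B1 and CYP19A1 were higher in KO clone 2 than in KO clone 1, by log2 2.29, 3.04 and 0.81. No steroidogenic gene was called between genotypes. Against the mean of the control clones, 1 was called higher and 1 lower in KO clone 1. In KO clone 2, 3 were called higher and 3 lower. The next members were chosen after their values were seen, and no GC trend was removed for them. STAR (-0.10, SE 0.25) and CYP17A1 (-0.07, SE 0.31) had values near 0, and CYP11A1 was at -0.44, SE 0.35. Adrenocortical identity and ACTH/cAMP genes (median 0.09, adjusted p = 0.354), filopodia and lamellipodia regulators (median -0.05, adjusted p = 0.335) and YAP/TEAD targets (median 0.11, adjusted p = 0.0903) did not pass. Hypoxia genes came nearest, at adjusted p = 0.0544 (adjusted p = 0.0125 with a GC trend removed).

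Compared with the mean of both control clones, KO clone 1 had 1078 genes called by limma, 608 higher and 470 lower, and KO clone 2 had 1887, 858 higher and 1029 lower. Of these, 150 were higher in both clones, 94 lower in both and 50 opposite. Independent lists of these sizes would share 34 higher and 31.6 lower, with 67.2 opposite. Simulated clones with no effect, sharing the controls, gave 16.22, 15.3 and 1.48, from shorter lists of 293.56 and 292.16 calls on average, so that these overlaps cannot be set against 150 and 94 directly. Across genes, which are not independent replicates, the KO clones' log2 changes correlated with r = 0.277 (covariance 0.0459), and the simulated values were 0.336 and 0.042. With a separate control clone for each, r was -0.03 or -0.13. The counts rested on which control clone was used: KO clone 1 had 2271 calls against control clone 1 and 195 against control clone 2, and KO clone 2 had 3284 and 387. Leaving out single libraries moved the count of KO clone 1 to 37 and 348 (without KO replicates 2 and 1), 476 and 583 (without control replicates 1 and 4), and 2133 and 2119 (without KO replicates 3 and 4). For KO clone 2 it became 721 and 3338 without KO replicates 3 and 4, and 1072 and 1064 without control replicates 1 and 3.

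The KO clones differed from each other at 1601 genes by limma, 657 higher and 944 lower in KO clone 2. The receptor phosphatase gene PTPRZ1 (log2 4.07), FUT1 (3.77), FGF21 (3.65), MYOT (3.09) and HOXB9 (3.03) were higher in KO clone 2, as was NLRP1 (3.16, from cultures at 546 and 220.4), which ranked among them but for its symbol, and SDK2 (-2.98), ALX4 (-2.88), TESC (-2.82), C17orf113 (-2.56) and SEZ6L (-2.39) were lower. Some of these folds rested on 1 culture of KO clone 2: without KO replicates 3 and 4 they were 2.62 and 4.92 for FUT1, 2.36 and 4.94 for FGF21, -1.003 and -4.95 for SDK2, and -1.74 and -4.03 for ALX4. The calls ended for FGF21 without KO replicate 1 (adjusted p = 0.0509), for SDK2 without KO replicate 1 or 2 (adjusted p = 0.139 and 0.173) and for ALX4 without KO replicate 2 (adjusted p = 0.0594). Aldosterone synthase, CYP11B2, averaged 104 normalised counts in KO clone 2 against 19.48 in KO clone 1, and HSD3B2 averaged 1588 against 355.9. Its cultures in KO clone 2 were far apart, at 935.4 and 2241. Cholesterol biosynthesis genes were lower in KO clone 2 than in KO clone 1 (median -0.48, cameraPR adjusted p = 4.49e-06; adjusted p = 0.831 with an estimated correlation). This rested on KO replicate 3, without which the median was -0.15 (adjusted p = 0.333); without KO replicate 4 it was -0.82. The count was 2609 without KO replicate 4, 536 without KO replicate 1 and 329 without KO replicate 2.

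The 2 control clones differed at 1258 genes, 515 higher and 743 lower in control clone 2, by limma. COLCA1 (log2 5.28), TUBA3D (4.26), ZBTB16 (3.55) and DGKB (2.88) were higher in control clone 2, and HOXB9 (-5.21), PTPRZ1 (-4.60), CPED1 (-4.36), FAM166B (-3.90) and TH2LCRR (-3.75) were lower. Without control replicates 3 and 4 these differences were 3.56 and 4.95 for TUBA3D, -4.46 and -5.96 for HOXB9, and -3.09 and -4.40 for TH2LCRR. Steroidogenic genes (median -0.23, adjusted p = 0.0188; adjusted p = 0.635 with an estimated correlation) and cholesterol biosynthesis genes (-0.36, adjusted p = 0.000816; adjusted p = 0.635 with an estimated correlation) were lower in control clone 2, with CYP11A1 at -1.26. Wnt/beta-catenin targets were higher (0.26, adjusted p = 0.000158; adjusted p = 0.635 with an estimated correlation). Without control replicate 4 the Wnt/beta-catenin median was 0.44. The steroidogenic call ended without control replicate 3 (adjusted p = 0.118). Other lists past the test were adrenocortical identity (median -0.25), cell cycle (-0.15), neuroendocrine markers (0.11) and ribosomal protein genes (0.14). None of these held in camera with an estimated correlation (adjusted p = 0.635 to 0.8). Of them, fry kept the neuroendocrine markers alone (fry adjusted p = 0.0123). Without control replicate 3, the cell cycle, neuroendocrine and ribosomal calls ended (adjusted p = 0.0798, 0.101 and 0.356). The neuroendocrine call also ended without control replicate 2 (adjusted p = 0.116) or KO replicate 3 (adjusted p = 0.0511), and the ribosomal median was -0.098 without control replicate 2 (adjusted p = 0.172). Without control replicates 1 and 4 the medians were 0.061 and 0.22 for neuroendocrine markers and 0.385 and 0.221 for ribosomal protein genes. The count was 472, 756, 539 and 709 without control replicates 1 to 4, and 2249 and 2248 without KO replicates 3 and 4. KO libraries enter this contrast only through the spread between cultures, which the fit pools over the clones. This spread was largest in KO clone 2 (SD of the log2 difference 0.442, against 0.341 to 0.356 in the other clones).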

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

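Tests of the SRF/MRTF and matrix lists in other pairings of the clones were chosen after the results were seen, as were the use of FSCN1 to judge sensitivity, the arm offset as the value for shared copy number, the test of whole chromosome arms, the results between KO clones without single libraries, the GC test of the matrix list, and adjusted p-values for the list without immediate-early genes and with a GC trend removed. The bounds set for the other pairings (adjusted p above 0.05 in both) and for sensitivity (over 50% called) would have excluded those explanations; both were set aside after the values were seen, for the reasons given below.

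The genotype test called 0 genes while DESeq2 called 126. For the counts of 0 the splits of the 8 libraries decide nothing, since all 35 must give at least 0 (highest other 14, and 13 of at least 2-fold). Chance cannot be excluded for the DESeq2 count, since 4 of 35 splits gave as many, the highest other being 609, in a split that pairs each KO clone with a control clone. The other split of that kind gave 320, so the real grouping gave the fewest calls among those that keep clones whole. The remaining splits put cultures of a clone on both sides. For the 7 separating genes, another pairing of clones gave 72, so differences between clones whatever their genotype could account for the count, while a GC trend is argued against, since 83.3% of those with a GC value still separated after its removal. A shared copy-number difference of whole arms is argued against. In the direction of the gene, the offset of an arm came to at most 10.1% of the change of a separating gene on it. The largest offset the other way was that of ORM1, at -15%. The genes of each pair on 7p (offset 0.005) and 9q (0.14), 57.1% of the 7, moved in opposite directions. A copy-number difference of a shorter segment stays open, as does a lack of power. The fit called 76.3% of simulated 2-fold changes, past the bound set in advance against a lack of power. Yet it did not call FSCN1 itself (limma adjusted p = 0.146).

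The SRF/MRTF and matrix lists were higher in KO by limma's cameraPR, though neither call held in camera with an estimated correlation (adjusted p = 0.088 for each). That test also had no clone block. For the matrix list its estimated correlation, 0.012, was near the preset 0.01, so the correlation alone does not explain the loss of that call. Only the real split of 35 gave these lists cameraPR p-values as small (9.6e-10 against 4.25e-05 at best, and 5.28e-06 against 3.41e-05). Most of the 35 splits put cultures of a clone on both sides, so 1 of 35 is not a chance rate for whole clones. Some list reached 9.6e-10 in 23 of the 35 splits, and these lists were picked out of 29. For the count of 9 lists, 2 of 35 splits gave as many (highest other 10), so that chance cannot be excluded for the count. Without its 5 immediate-early genes the SRF/MRTF list kept a limma cameraPR adjusted p of 7.66e-05, with a median of 0.305 against 0.41. These genes were thus not the whole of the call. A response at harvest that also moved the other members cannot be excluded this way. With a GC trend removed, the limma cameraPR adjusted p was 2.71e-06 for the SRF/MRTF list and 0.00235 for the matrix list. This argues against GC bias as the whole cause. The trend's removal lowered the medians of the same members from 0.41 to 0.30 and from 0.30 to 0.20, so GC bias may account for part. All these p-values come from cameraPR at the preset correlation. Differences between clones whatever their genotype cannot be told apart from genotype, because 4 clones allow only 3 pairings; the smaller adjusted p of the lists in the other pairings was 0.362 and 0.778. A change in SRF/MRTF activity after loss of fascin is a hypothesis that stays open.

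Clones of the same genotype differed at 1601 genes (KO) and 1258 genes (control). Differences in copy number may contribute: the median of 190 genes on 4p was offset by -0.253 between control clones, and that of 9p by -0.20 between KO clones. On 4p lay 39 of the 1258 genes and on 9p 24 of the 1601, so these arms could account for few of them. The next largest offset between control clones was 0.177, on 9q, with 53 of the genes. Selection or drift during cloning was not tested.

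Several results differed between the KO clones by limma's test of the difference, among 133 genes: the genes that separated the clones, those given for both KO clones, and up to 4 members of each list. In log2 of KO clone 2 minus KO clone 1, they were FOS (1.29), EGR1 (1.23), FN1 (0.80), FAM83G (0.63), COL3A1 (2.65), ACTA2 (0.50), ABCA1 (0.81), PSAT1 (0.86), CACNA1H (0.73), CYP11B2 (2.29), CYP19A1 (0.81), HSD3B1 (3.04), ITGB5 (1.09), MMP24 (1.28), HLA-B (0.87) and EMCN (2.03), all higher in KO clone 2. FSCN1 (-0.89), ATCAY (-0.95), RIMS4 (-1.45), CTNNA3 (-0.85), FBLN1 (-0.65), ITGA2 (-0.57), CDH23 (-1.03) and SNAP25 (-0.83) were lower in KO clone 2. These are 24 of the 133 genes. All 24 kept their direction without any single library, but 5 alone (FSCN1, RIMS4, COL3A1, CYP11B2 and ITGB5) also kept their call. Calls ended for 14 genes without KO replicate 1, 15 without KO replicate 2, 5 without KO replicate 3, 1 (ACTA2) without KO replicate 4 and 1 (FAM83G) without any one of the control replicates, with limma adjusted p of 0.0506 to 0.343. The value of COL3A1 was 1.92 without KO replicate 3 and 3.38 without KO replicate 4.

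The lists that differed between the KO clones were cholesterol biosynthesis (median -0.48), axon guidance (-0.23), unfolded protein and stress response (0.26), growth factor signalling (0.09), ribosomal protein genes (0.19) and histones (0.13). None of these calls held with an estimated correlation (limma camera adjusted p = 0.831 for each). Of them, fry kept growth factor signalling alone (fry adjusted p = 0.00351). Without KO replicate 3, culture 1 of KO clone 2, the calls ended for cholesterol (median -0.15, limma cameraPR adjusted p = 0.333), stress response (0.05, adjusted p = 0.408), ribosomal protein genes (0.10, adjusted p = 0.145) and histones (0.095, adjusted p = 0.199). Those for ribosomal protein genes and histones also ended without KO replicate 1 (limma cameraPR adjusted p = 0.504 and 0.964), and that for growth factor signalling without KO replicate 4 (adjusted p = 0.105). Medians also moved where the call stayed: growth factor signalling to 0.027, 0.024 and 0.047 without KO replicates 1, 2 and 3, and, without KO replicate 4, cholesterol to -0.82 and stress response to 0.52. Without KO replicates 2 and 4 they were 0.282 and 0.28 for ribosomal protein genes and 0.252 and 0.201 for histones.

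Some groups of 4 libraries held a value far from the rest, by the gap to its nearest neighbour over the range, against Dixon's limit for 4 values. In KO libraries, culture 1 of KO clone 2 was the far library for NSUN5 (0.838), HCRTR2 (0.846), HSD17B12 (0.831), ACAT2 (0.873), CHGB (0.915), and the scores of Wnt/beta-catenin targets (0.888) and of stress response genes (0.874). Culture 2 of KO clone 2 was far for the scores of steroidogenic (0.841) and adrenocortical identity genes (0.835), culture 1 of KO clone 1 for BAX (0.862) and its culture 2 for NOTCH1 (0.933). In control libraries, culture 1 of control clone 2 was far for PSAT1 (0.933) and OCLN (0.926), its culture 2 for MMP24 (0.88), and culture 1 of control clone 1 for the score of mesenchymal markers (0.933). These are 15 of 330 groups tested, and about 1 in 20 passes by chance.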

How the results depend on the processing

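The count of genes separating the clones, the fits against a single control clone, DESeq2 without a filter, the GC trend, the actin list without FSCN1, and the lists between clones without single libraries were chosen after seeing the data. FSCN1 was lower in KO in every fit run, from -0.998 to -1.89. Its call appeared under DESeq2 (-1.37), without KO replicate 3 (-1.28), without control clone 2 (-1.41), without KO clone 1 (-1.89) and without KO clone 2 (-0.998); leaving out single libraries gave -1.28 to -1.56. The genotype count of 0 held under the other pseudocounts, filters and scalings, the prior without a trend and clone means. It was 2 without the clone block, 2 with edgeR, 126 with DESeq2 and 113 with DESeq2 without a filter; of at least 2-fold, 2, 2 and 43. It was 2 without control clone 1, 312 without control clone 2, 2 without KO clone 1 and 15 without KO clone 2 (at least 2-fold: 2, 201, 2 and 12), and 0 to 6 when single libraries were left out (0 to 6 at least 2-fold). In each fit without a clone, that genotype kept 1 clone, so genotype and clone cannot be told apart, for FSCN1 as for these counts. For the 312, the control left was control clone 1. Against it the KO clones had 2271 and 3284 calls in the 4-clone fit, and 195 and 387 against control clone 2. The cause was not tested further. Of 3494 values for named genes, 3485 kept their direction; the other 9 were not called either way. Among the genes named for the largest differences between the KO clones, 9 such calls were lost (4 of SDK2, 2 each of FGF21 and ALX4 and 1 of FUT1). Of these 9, 4 were lost when single libraries were left out. Calls between KO clones that other named genes lost without single libraries are given above and are not among the 9. Over all named genes, 86 calls were gained, 33 of them under DESeq2 and 41 without control clone 2.

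The 9 list calls became 4 with a prior without a trend, 4 without the clone block, 5 without KO clone 1, 0 with an estimated correlation and 2 with fry, and 5 to 11 when single libraries were left out (5 without control replicate 1 or 3 or KO replicate 1). The 2 with fry were the SRF/MRTF and fibroblast lists. The SRF/MRTF list passed in 25 of 26 alternatives (medians 0.30 to 0.53) and the matrix list in 24 of 26 (0.20 to 0.36). With a GC trend removed the list count was also 9, of 28 lists, since no histone gene was tested there: the axon guidance and Wnt/beta-catenin calls ended, and hypoxia (adjusted p = 0.0125), mesenchymal (adjusted p = 0.0204) and ribosomal protein genes (adjusted p = 0.0291) passed. The cholesterol list turned in its test without KO replicate 3 (median -0.044, the range over single libraries being -0.366 to -0.044), without control clone 1 (-0.074) and without KO clone 2 (0.022), axon guidance without KO clone 1 (-0.117) and stress response without KO clone 1 (0.029); the cause was not tested.

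For KO clone 1 against controls, the count was 529 without a filter, 204 with a prior without a trend, 2271 and 195 against control clones 1 and 2 alone, and 37 to 2133 when single libraries were left out. For KO clone 2 these were 1152, 556, 3284, 387 and 721 to 3338. Between KO clones they were 925, 368 and 329 to 2609, between control clones 793, 555 and 472 to 2249, and for separating genes 4, 3 and 1 to 40. No scaling moved the share of higher calls by over 10 percentage points (largest -5.3) or the median of all genes by over 0.1. Depth was similar in all libraries and limits mainly genes near the minimum of 10.

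With the culture number as a replicate block, the genotype count was 0, the list count 10, and the counts for KO clones 1 and 2 were 939 and 1709. The deviations of same-numbered cultures correlated by -0.132 to 0.096, so no strong effect shared by these cultures was seen. Whether same-numbered cultures were handled together cannot be told from this. Between clones, the histone list turned in its test without KO replicate 1 (range over single libraries 0.017 to 0.252) and the ribosomal protein list of the control clones without control replicate 2 (-0.098 to 0.385); the cause was not tested.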

Other observations

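The genes given here were chosen after their values were seen, and no shared function was tested for them. TGFB2, a TGF-beta ligand, averaged 700.7 and 1036 normalised counts in control clones and 1443 and 1169 in KO clones 1 and 2. NOTCH1 averaged 478.5 and 910.7 against 1100 and 1016. For TGFB2 and NOTCH1, control clone 2 lay nearer to both KO clones than control clone 1 did. The R-spondin receptor LGR5 averaged 131 and 439.7 against 395.1 and 406.2, so that control clone 2 was no lower than the KO clones. All 3 were called by limma in both contrasts of a KO clone with the mean of the control clones, with the largest adjusted p at 0.0247, and none in the genotype test.

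Without overlap of KO and control libraries were 1089 genes, 563 higher and 526 lower, or 7.11% against 2.86% by chance for independent libraries. The other pairings of the clones gave 1478 and 950.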
